A study of Homo sapiens with 18 samples.

How the data were processed

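Messenger RNA was measured in 18 libraries of HMC3 cells, a human microglial cell line, after 24 h with oxidized low-density lipoprotein (oxLDL) at 100, 50, 10, 2.5, 1 or 0 µg/ml, with 3 libraries at each of the 6 doses. Per the labels, total RNA was extracted with TRIzol, mRNA was enriched on poly-T beads, and libraries made with a NEBNext Ultra kit were sequenced as paired ends on a NovaSeq. The named kit does not mark strand, and the sources used here do not say how strand was treated in counting, so genes that overlap another gene on the opposite strand carry reads that cannot be assigned to 1 of them with certainty. The labels give 1 batch value for all libraries.

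The deposited table holds FPKM (fragment numbers scaled by transcript length and by library total) for 13992 gene symbols in each of the 18 libraries. The submitters' processing notes name HISAT2 2.0.5, featureCounts, DESeq2 and the genome build hg38, without stating the role or the order of each. The annotation release and the rule by which genes were listed are not stated. That the values are FPKM was checked from their steps. For each library and gene, the FPKM values were whole multiples of 1 step, so whole read numbers could be recovered within 0.05 reads in all libraries for 13990 genes (99.99%). The lengths this gave were compared with RefSeq for 362 single-exon genes, and 69.6% were equal. Recovered depths were about 13919066 to 37382244 per library, with an absolute scale that rests on these lengths. Whether they are reads or fragments is not stated. The listed genes held 99.87% to 99.89% of each total, and the sums of FPKM per library were 386396 to 413363. The lowest mean of a listed gene was 4.17 reads per library, and 15 values were exactly 0. Counting error is the lower limit of the error of each value, and reads without molecular identifiers are not independent molecules.

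Genes with FPKM of at least 0.5 in at least 3 of the 18 libraries were tested (12127 genes), and 1865 fell below this filter. Values were log2(FPKM + 0.5), a scale that understates the change of genes with low FPKM. All 6 doses were fitted together in limma 3.58.1 (R 4.3.3), with 1 mean per dose, 12 residual degrees of freedom and the eBayes variance trend. Each dose was compared with 0 µg/ml, and each dose from 2.5 µg/ml with the dose before it. A test over all doses and a slope on log2(dose + 1) were added. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with the limma standard error (SE), and FPKM as mean ± SD. The fit takes library totals as deposited, with no further scaling. Count models such as DESeq2 were not run, because the deposited unit is FPKM. The recovered reads were used only in other settings below, among them limma-voom.

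Gene lists numbering 32 were fixed: scavenger and lipoprotein receptors, fatty acid uptake and lipid droplet, cholesterol biosynthesis (SREBP2), fatty acid synthesis (SREBP1), LXR targets and cholesterol efflux, PPAR targets and fatty acid oxidation, NRF2 targets and oxidative stress, NLRP3 inflammasome and IL-1, NF-kB cytokines and chemokines, interferon response, integrated stress response (ATF4), unfolded protein response, heat shock proteins, lysosome and autophagy (TFEB), ferroptosis and iron, metallothioneins, hypoxia and glycolysis, nuclear genes of the mitochondrial respiratory chain, mitochondrially encoded transcripts, ribosomal proteins, DNA replication and S phase, mitosis and G2/M, p53 targets and apoptosis, immediate early genes, extracellular matrix and TGF-beta, and markers of microglia and macrophages, disease-associated microglia, astrocytes, neurons, oligodendrocytes, pericytes and fibroblasts, and endothelium. Lists with at least 5 tested genes (29) were compared with all other tested genes by camera, with a preset correlation between genes of 0.01, at each dose against 0 µg/ml. These 145 tests were adjusted together. Each was repeated with the correlation estimated from the data. Some lists share genes, so their tests are not independent.

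Genes are named by a rule. Among called genes with a mean FPKM of at least 1 at either dose and all 3 libraries of one dose above all 3 of the other, the 8 largest rises and 8 largest falls are named at 50 and 100 µg/ml, 5 and 5 at the lower doses, and 3 and 3 between adjacent doses. Clone names and unnamed loci were left out. For each list, up to 4 members with the smallest adjusted p are named, and for the slope the 5 steepest rises and falls with a mean FPKM of at least 1. CD36, NLRP3, IL1B, CASP1, PYCARD, IL18, PLIN2, HMOX1, ABCA1 and HMGCS1 were fixed by name. Where a list held 5 or fewer called genes in a direction, the remaining ones are also named, and these were chosen after their values were seen. The lists of scavenger receptors and of microglia and macrophage markers are given at 100 µg/ml by their counts alone. The samples and their groups, the tests, the filter, the lists, the naming rule and the first group of other settings below were set before the data were examined.

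Other settings, each tried 1 at a time, were each library left out in turn, a fit of 2 doses only, dose coded by rank or linearly, robust eBayes, eBayes without the trend, array weights, a filter of FPKM of at least 1, no filter, a minimum absolute log2 fold change of 1, replicate number as a block, an estimated correlation, pseudocounts of 0.1 and 1, median-ratio scaling, quantile normalization and TPM rescaling. Chosen after the data were seen were limma-voom on the recovered reads, recovered reads thinned to the depth of the shallowest library, removal of each library's trend with gene length and GC content, a fit without the 3 libraries farthest from their group on the first 3 principal components, and lists without the genes they share with the NRF2 list, with the preset and with an estimated correlation. Positions came from RefSeq on hg38 for 13728 symbols (98.11%), and GC content from GENCODE release 29 for 12224 symbols (87.36%). Gene lengths were those recovered together with the read numbers.

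The fit was tested on simulated data in which genes of known change were placed at 100 µg/ml (12081 genes tested). It recovered 72% of 1.25-fold, 94% of 1.5-fold, 100% of 2-fold and 95.9% of 3-fold changes, with about 50 genes at each size. Of 188 calls, 8 (4.3%) were false, and 0 calls were made at a simulated dose without change. Genes were simulated independently of each other, without effects shared across a library, so these rates may not hold for the real libraries. Because every dose shares the same 3 libraries at 0 µg/ml, overlap between doses was set beside 100 simulations with unchanged groups. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15.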

Results

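HMC3 cells, an immortalized line used as a model of human microglia, were exposed for 24 h to oxLDL, a lipoprotein particle taken up through scavenger receptors. The series concerns CD36, lipid accumulation in reactive microglia, and retinal degeneration through Nlrp3 and IL-1β. This dose series asks how transcripts of the cell line change with the amount of oxLDL. Poly-A RNA was sequenced in 18 libraries, 3 at each dose. Recovered depths, as total reads, were about 20560004, 27011700 and 27908485 at 0 µg/ml and 20184161, 21147265 and 20145419 at 1 µg/ml. They were 20634055, 16203259 and 21342852 at 2.5 µg/ml, and 20904631, 18639254 and 25947041 at 10 µg/ml. At 50 µg/ml they were 32871998, 24668367 and 18996130, and at 100 µg/ml 17908488, 37382244 and 13919066. The labels do not say that the libraries of a dose came from separate cultures, so each p-value measures the spread between these libraries, which may be technical. FPKM values below are mean ± SD over 3 libraries of a dose, folds are log2 fold changes with the limma SE, and p-values are adjusted by Benjamini-Hochberg.

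Transcripts changed mainly at 50 and 100 µg/ml. Of 12127 genes tested, 906 were called at 50 µg/ml (458 up, 448 down) and 1874 at 100 µg/ml (963 up, 911 down). At 10 µg/ml 5 genes were called (4 up, 1 down), with 1185 genes at an unadjusted p under 0.05. At 1 and 2.5 µg/ml limma called 0 genes, with 365 and 531 genes at an unadjusted p under 0.05 where about 606 would arise by chance at any dose, and limma-voom also called 0 at both. Most changes were small: the median absolute fold of called genes was 0.25 at 50 µg/ml and 0.24 at 100 µg/ml, and 9 and 29 of them had an absolute fold of at least 1.

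**Figure D1:**
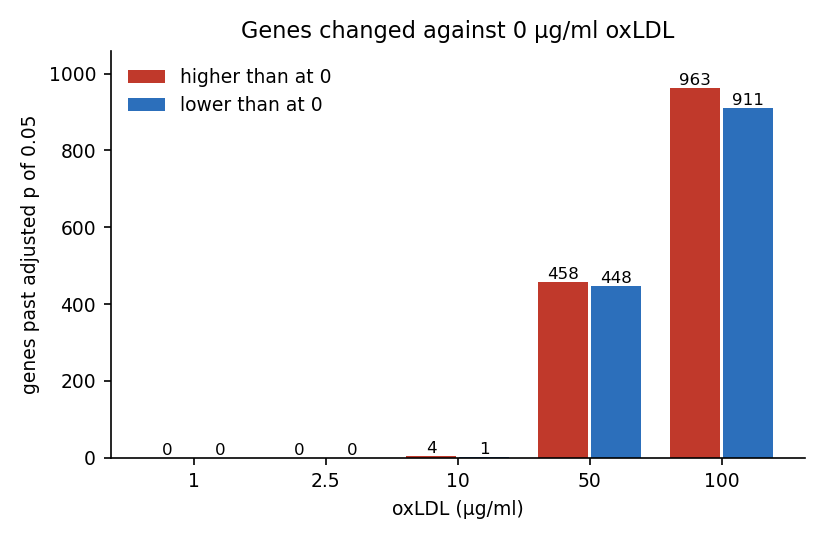
Bars give the number of genes with higher (up) or lower (down) FPKM than at 0 µg/ml, at an adjusted p under 0.05, for each oxLDL dose in µg/ml. Calls rise from 0 at 1 and 2.5 µg/ml to 963 up and 911 down at 100 µg/ml.

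At 100 µg/ml the largest rise was in ANGPTL4, which encodes a secreted inhibitor of lipoprotein lipase (hg38 chromosome 19, 8364155 to 8374370). Its FPKM went from 0.228 ± 0.077 at 0 µg/ml to 8.70 ± 0.94, a fold of 3.66 (SE 0.16, adjusted p = 1.02e-10) and a ratio of means of 38.2. ANGPTL4 overlaps RAB11B-AS1 on the opposite strand. SLC7A11, the light chain of the cystine and glutamate exchanger (chromosome 4, 138164097 to 138242349), rose from 1.36 ± 0.055 to 9.15 ± 0.66 (fold 2.38, SE 0.063, adjusted p = 2.31e-13). HMOX1, which degrades heme (chromosome 22, 35381096 to 35394207), rose from 9.18 ± 0.36 to 43.4 ± 2.6 (fold 2.18, SE 0.068, adjusted p = 9.08e-13). OSGIN1, an oxidative stress response gene (chromosome 16, 83953240 to 83966332), rose from 3.55 ± 0.14 to 13.4 ± 0.6 (fold 1.78). GCLM, a subunit of the enzyme that starts glutathione synthesis (chromosome 1, 93885199 to 93909430), rose from 5.39 ± 0.43 to 16.6 ± 0.19 (fold 1.54). NQO1, a quinone reductase (chromosome 16, 69709401 to 69726560), rose by a fold of 1.52 to 179.5 ± 7.1. The matrix metalloproteinases MMP1 (fold 1.42, SE 0.36, adjusted p = 0.0123) and MMP3 (fold 1.40, SE 0.17, adjusted p = 3.47e-05) also rose. MMP1 lost its call without replicate 3 at 100 µg/ml (adjusted p = 0.0766) and without replicate 1 at 0 µg/ml (adjusted p = 0.0527).

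The largest falls at 100 µg/ml were in MDGA1, a membrane-anchored adhesion protein (fold -1.25, SE 0.20), the microRNA host transcript MIR503HG (-1.15, SE 0.08), and OLR1, the lectin-like receptor for oxLDL (-1.14, SE 0.19). FPKM of OLR1 (chromosome 12, 10158301 to 10176266) was 2.94 ± 0.49 at 0 µg/ml and 1.06 ± 0.23 at 100 µg/ml (adjusted p = 0.000685). EGR1, an immediate early transcription factor (chromosome 5, 138465479 to 138469303), went from 9.70 ± 1.2 to 4.17 ± 0.68 (fold -1.13, adjusted p = 0.00119). TINAGL1, a secreted matrix protein (chromosome 1, 31576515 to 31587686), went from 37.4 ± 0.72 to 16.8 ± 1.3 (fold -1.13, adjusted p = 1.36e-10). ELF3, an epithelial transcription factor that overlaps ELF3-AS1 on the opposite strand, the Wnt ligand WNT7B, and NPPB, the precursor of a natriuretic peptide, fell with folds of -1.12, -1.08 and -1.06.

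**Figure D2:**
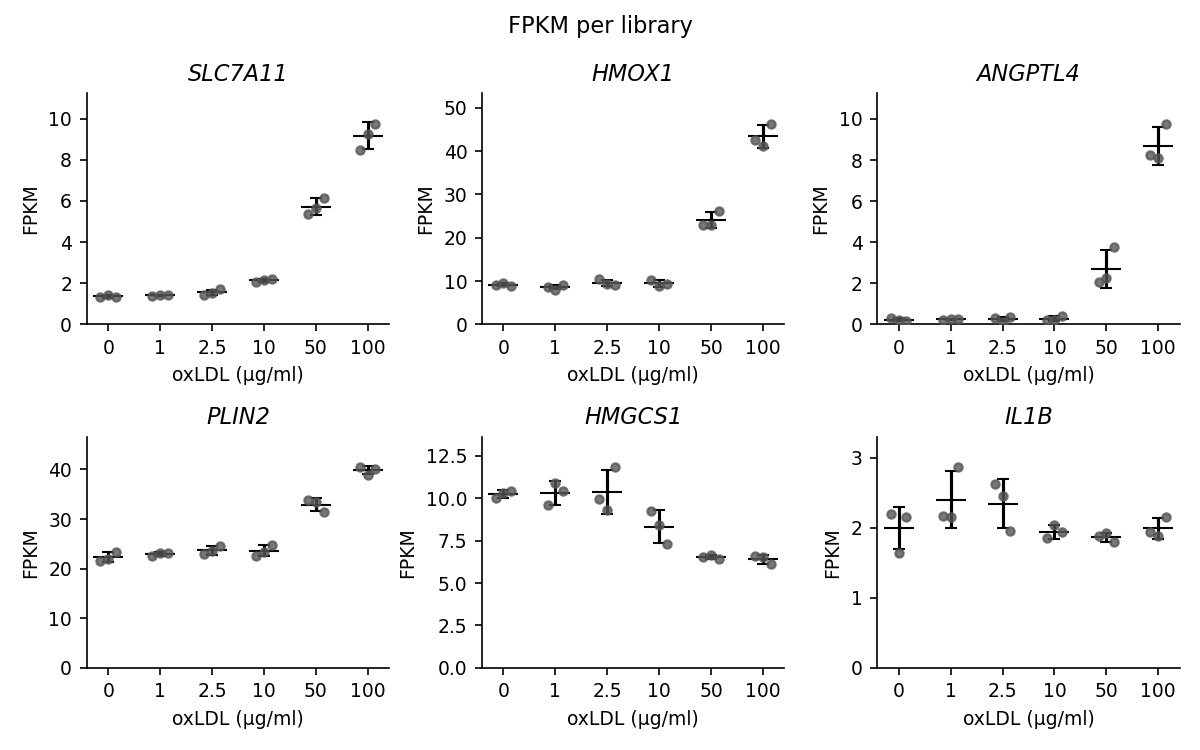
FPKM of SLC7A11, HMOX1, ANGPTL4, PLIN2, HMGCS1 and IL1B against oxLDL dose in µg/ml, where points are libraries and bars the mean ± SD of 3 libraries. HMOX1 reaches 43.4 and ANGPTL4 8.70 at 100 µg/ml, HMGCS1 drops to 6.41, and IL1B stays between means of 1.86 and 2.40.

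Targets of NRF2, the transcription factor of the antioxidant response, rose as a group at 100 µg/ml. Of 27 tested members 24 rose and 0 fell (25 and 1 when adjusted over the list alone), with a median fold of 0.61 (camera adjusted p = 3.26e-39). The count holds TRIM16 and TRIM16L, near-identical paralogs whose reads cannot be assigned with certainty. Beside SLC7A11, NQO1 and HMOX1, the selenoprotein reductase TXNRD1 rose from 120 ± 6.6 to 288 ± 9.2 FPKM (fold 1.26). The ferroptosis and iron list rose too, with 8 members up and 1 down of 21 (10 and 1 adjusted over the list alone; camera adjusted p = 1.25e-06). Its risers included the ferritin light chain FTL, from 2058 ± 74 to 3858 ± 177 FPKM (fold 0.91), and the transferrin receptor TFRC, from 55.0 ± 3.5 to 94.2 ± 3.7 (fold 0.77). GPX4, the peroxidase that protects membranes from lipid peroxides, was the member that fell (fold -0.26, adjusted p = 0.00291), and was named after its value was seen. Without the genes shared with the NRF2 list, the remaining 17 genes of this list had a camera adjusted p of 0.0154. That call was lost at adjusted p = 0.0836 with an estimated correlation.

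Among lipid genes, PLIN2, which coats lipid droplets, rose from 22.3 ± 0.98 to 39.8 ± 0.83 FPKM at 100 µg/ml (fold 0.82, adjusted p = 4.82e-10). The list of PPAR targets and fatty acid oxidation genes had 7 members up and 2 down of 20 (7 and 3 adjusted over the list alone; camera adjusted p = 0.00138). The median fold of this list was 0.041 and its mean 0.324, with 12 members above 0 and 8 below. Its risers included ANGPTL4, PLIN2 and CPT1A, which brings fatty acids into mitochondria (2.81 ± 0.097 to 5.57 ± 0.027 FPKM, fold 0.88). ACADVL, an acyl-CoA dehydrogenase that overlaps DLG4 on the opposite strand, rose too (fold 0.38). The falling members were CPT2 (-0.23, adjusted p = 0.0176) and HADHA (-0.10, adjusted p = 0.0253), further enzymes of fatty acid oxidation named after their values were seen. Both calls were lost in some settings, CPT2 in 5 of 33 (highest adjusted p = 0.104, thinned reads) and HADHA in 8 (0.13, without replicate 3 at 100 µg/ml). The wider list of fatty acid uptake and lipid droplet genes was not called (19 tested, 4 up and 1 down, 5 and 2 adjusted over the list alone, camera adjusted p = 0.303). In it PLIN2, the lipolysis inhibitor G0S2 (fold 0.67), SOAT1, which esterifies cholesterol (0.26), and the lipase MGLL (0.23, chosen after its value was seen) rose, and the lipase PNPLA2 fell (-0.15). MGLL and PNPLA2 lost their calls in 3 settings each, at most at adjusted p of 0.0636 and 0.0607.

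Cholesterol biosynthesis genes under SREBP2 were lower at 100 µg/ml: of 24 members 16 fell and 0 rose (20 and 0 adjusted over the list alone), with a median fold of -0.29. The camera adjusted p was 1.43e-13 with the preset correlation, and the call was lost at adjusted p = 0.0906 with an estimated correlation. HMGCS1, an early enzyme of the pathway, went from 10.3 ± 0.22 to 6.41 ± 0.27 FPKM (fold -0.64, adjusted p = 4.13e-05). INSIG1, a sterol sensor, went from 17.4 ± 0.96 to 10.4 ± 1.0 (fold -0.72), and ACAT2, which overlaps SOD2 and TCP1 on the opposite strand, had a fold of -0.38.

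The list of SREBP1 fatty acid synthesis genes was not called at 100 µg/ml (17 tested, camera adjusted p = 0.0769), with 2 up and 5 down (3 and 6 adjusted over the list alone). Without ME1, which the NRF2 list also holds, the remaining 16 genes were called lower at 100 and at 50 µg/ml (camera adjusted p = 0.0125 at each). These calls were lost at adjusted p = 0.456 at each dose with an estimated correlation. SCD, the stearoyl-CoA desaturase, fell from 42.6 ± 0.74 to 23.3 ± 1.9 FPKM (fold -0.86), with FADS2 (-0.54), SREBF1 (-0.41), FASN (-0.40) and LPIN1 (-0.21), while ME1 (0.58) and ELOVL1 (0.13) rose. FADS2 overlaps other listed genes, and FASN, LPIN1 and ELOVL1 were chosen after their values were seen. LXR targets and cholesterol efflux genes went both ways (15 tested, 3 up and 3 down over all genes and adjusted over the list alone, camera adjusted p = 0.974): ABCA1, a cholesterol exporter (0.23, adjusted p = 0.0426), NR1H2 (0.17) and NPC1 (0.19) rose, and SCD, SREBF1 and ABCA7 (-0.28) fell. ABCA1 had 0.566 ± 0.059 FPKM at 0 µg/ml and 0.753 ± 0.052 at 100 µg/ml, and lost its call in 14 of 33 settings, among them without replicate 3 at 0 µg/ml (adjusted p = 0.148) and without replicate 3 at 100 µg/ml (0.145). NPC1, chosen after its value was seen, lost its call in 14 (at most 0.196), ABCA7 in 6 (0.148), LPIN1 in 6 (0.11) and ELOVL1 in 3 (0.0737).

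**Figure D3:**
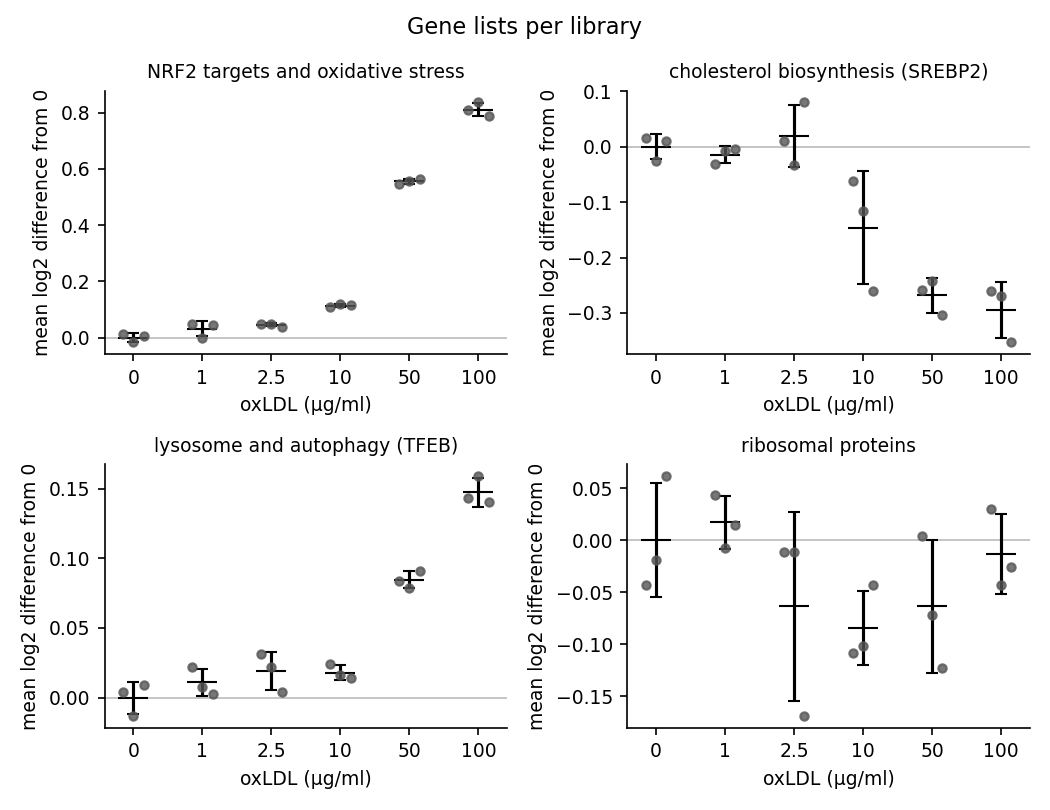
Mean log2 difference from the mean at 0 µg/ml over the genes of 4 lists (NRF2 targets, cholesterol biosynthesis, lysosome and autophagy, ribosomal proteins), against oxLDL dose in µg/ml, with points for libraries and bars for the mean ± SD of 3 libraries. The cholesterol biosynthesis libraries at 100 µg/ml lie at -0.26, -0.27 and -0.35, and 1 library at 10 µg/ml at -0.26 apart from the other two at -0.06 and -0.12.

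Of the genes of the series title, only IL1B was tested, and it was not called at any dose. CD36 and PYCARD were not among the symbols listed, so neither could be tested. NLRP3 was under the expression filter and was not tested, with 0.206 ± 0.025 FPKM at 0 µg/ml, 0.366 ± 0.052 at 50 µg/ml and 0.308 ± 0.12 at 100 µg/ml from 13 to 78 reads per library. IL1B was tested from 52 to 122 reads per library, and its FPKM was 2.0 ± 0.30 at 0 µg/ml and 1.99 ± 0.15 at 100 µg/ml (fold 0.004, SE 0.106, adjusted p = 0.989), so no difference was detectable at this depth. CASP1 had 0.595 ± 0.046 and 0.583 ± 0.045 FPKM (adjusted p = 0.93). IL18, a cytokine that CASP1 matures, rose from 14.2 ± 0.46 to 19.1 ± 3.4 FPKM at 100 µg/ml (fold 0.40, SE 0.091, adjusted p = 0.00589). The inflammasome and IL-1 list as a whole was not called (12 of its 22 genes tested, 3 up and 1 down over all genes and adjusted over the list alone, camera adjusted p = 0.353). Beside IL18, the inflammatory caspase CASP4 (0.52) and the sensor NLRP1 (0.25) rose and TXNIP, a thioredoxin inhibitor, fell (-0.35). CASP4 lost its call with reads thinned to equal depth (adjusted p = 0.141), and NLRP1 without replicate 2 at 100 µg/ml (0.0618) or replicate 1 or 3 at 0 µg/ml (0.0567 and 0.0528).

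Other inflammatory genes moved in both directions at 100 µg/ml. The NF-kB cytokine list was not called (19 tested, 4 up and 4 down, 4 and 5 adjusted over the list alone, camera adjusted p = 0.818), and its test and mean fold pointed up (0.13) with a median fold of -0.015. The cytokine IL11 rose from 32.8 ± 1.1 to 69.1 ± 1.1 FPKM (fold 1.06, adjusted p = 3.96e-13) with MMP1, MMP3 and the chemokine CXCL1 (0.41), and LIF (-0.58), NFKBIA (-0.41), TNFAIP2 (-0.23) and NFKB2 (-0.21) fell. CXCL1, MMP1, TNFAIP2 and NFKB2 complete this count and were chosen after their values were seen. CXCL1, TNFAIP2 and NFKB2 lost their calls in 14, 5 and 15 of 33 settings (at most adjusted p = 0.165, 0.107 and 0.151). Scavenger and lipoprotein receptors were not called as a list (11 of 22 tested, 2 up and 2 down, 3 and 2 adjusted over the list alone, camera adjusted p = 0.687; the test and the median fold of 0.018 pointed up, the mean of -0.008 down). Interferon response genes were lower, with 6 of 27 down and 0 up (9 and 0 adjusted over the list alone), among them IFIT1 (-0.51), IFIT2 (-0.40, with LIPA on the opposite strand), IFI44 (-0.34) and IFIT3 (-0.28). The camera adjusted p was 0.000556, and 0.178 with an estimated correlation, where the call was lost. IFI44 lost its call without replicate 1 at 0 µg/ml (adjusted p = 0.0532), and IFIT3 without replicate 2 or 3 at 0 µg/ml (0.0554 and 0.0623) or replicate 3 at 100 µg/ml (0.0735).

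Lysosome and autophagy genes rose at 100 µg/ml, with 17 of 34 up and 0 down (20 and 0 adjusted over the list alone; camera adjusted p = 4.73e-09). The galactosidase GLA went from 20.8 ± 0.82 to 34.7 ± 1.9 FPKM (fold 0.73) and the protease CTSL from 37.0 to 54.9 (0.56), with MAP1LC3B (0.28), which overlaps FBXO31 on the opposite strand. Integrated stress response genes rose (12 up and 1 down of 29; 14 and 3 adjusted over the list alone; camera adjusted p = 0.000285, and 0.0035 without NRF2 genes, or adjusted p = 0.05 with an estimated correlation, just under the threshold). Besides SLC7A11 they included its heavy chain SLC3A2 (0.54), the phosphatase subunit PPP1R15A (0.59) and CEBPB (0.60, with CEBPB-AS1 on the opposite strand), while SLC7A5, another partner of SLC3A2, fell (-0.57, adjusted p = 0.000344, named after its value was seen). Heat shock genes had 8 up and 0 down of 16 (12 and 0 adjusted over the list alone), with HSPH1 (0.33), HSP90AA1 (0.26), FKBP4 (0.20) and AHSA1 (0.16). Their camera adjusted p was 3.05e-06, and the call was lost at adjusted p = 0.0649 with an estimated correlation.

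Genes of DNA replication fell at 100 µg/ml: 13 of 43 were down and 0 up (23 and 0 adjusted over the list alone; camera adjusted p = 1.85e-07). MCM7, a subunit of the replicative helicase that overlaps AP4M1 on the opposite strand, went from 177 ± 4.6 to 118 ± 3.6 FPKM (fold -0.59), with LIG1 (-0.25), MCM6 (-0.20) and UHRF1 (-0.19). Mitosis genes had 9 down and 0 up of 40, the same numbers adjusted over the list alone, with KIF20A (-0.27, with BRD8 and CDC23 on the opposite strand), MYBL2 (-0.23), KIF23 (-0.16) and NUSAP1 (-0.12, lost without replicate 2 at 0 µg/ml, adjusted p = 0.0558). The mitosis list had a camera adjusted p of 0.000683, and 0.517 with an estimated correlation, where the call was lost. The p53 list rose with 12 up and 2 down of 29 (16 and 4 adjusted over the list alone; camera adjusted p = 0.000482). The cell cycle inhibitor CDKN1A went from 48.8 to 68.5 FPKM (fold 0.49), with TNFRSF10B (0.31) and AEN (0.30), while PLK2 (-0.47) and TP53I3 (-0.16) fell. TP53I3 was named after its value was seen and lost its call in 13 of 33 settings (at most adjusted p = 0.313).

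Immediate early genes rose as a list (14 up and 2 down of 29; 16 and 3 adjusted over the list alone; camera adjusted p = 3.95e-08). The phosphatase DUSP5 went from 11.4 to 24.1 FPKM (fold 1.05) and the matricellular protein CCN2 from 204 ± 7.2 to 338 ± 9.9 (0.73), with DUSP4 (0.82) and SPRY4 (0.77). The members that fell were the transcription factors EGR1 and JUND (-0.51, adjusted p = 0.000285, named after its value was seen). Extracellular matrix genes had 3 up and 16 down of 35 (4 and 17 adjusted over the list alone), with CCN2, LOX (0.34) and MMP14 (0.34, named after its value was seen) up and THBS2 (-0.53) and BGN (-0.44) down. Their camera adjusted p was 0.000419, and the call was lost at adjusted p = 0.56 with an estimated correlation.

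No marker list was called at 100 µg/ml. Of 33 markers of microglia and macrophages, the cells the line is used to model, 7 were tested, with 1 up and 2 down. Adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.811, with a median fold of 0.10 and a mean of -0.03). Among 12 disease-associated microglia genes (3 up and 0 down over all genes and adjusted over the list alone, camera adjusted p = 0.204, with a median fold of -0.01 and a mean of 0.12) the cathepsins CTSL, CTSD (0.20) and CTSB (0.19) rose. The CTSB call was lost in 5 settings (at most 0.11, without replicate 2 at 0 µg/ml). Pericyte and fibroblast markers (12 tested, 0 up and 3 down over all genes and adjusted over the list alone, camera adjusted p = 0.136) were expressed at high levels, with COL1A1 at 496 ± 25 FPKM and THY1 at 96.5 FPKM at 0 µg/ml. COL1A1 (-0.48), THY1 (-0.38) and PDGFRB (-0.51) fell. Astrocyte (9 tested, camera adjusted p = 0.233) and neuron markers (5 tested, 0.815) were not called, and the oligodendrocyte and endothelial lists had too few tested genes (3 and 4).

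The call count at 100 µg/ml dropped to 1204 without replicate 3 of that dose. All 13 lists called at 100 µg/ml with the preset correlation kept their call in 33 of 33 settings, all with that correlation. With an estimated correlation 8 of the 13 lists were called. Other splits of the libraries at 0 and 100 µg/ml called up to 13 lists with the preset correlation and 0 with an estimated one.

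At 50 µg/ml 13 lists were called. The p53 (29 tested, 5 up and 2 down, 7 and 2 adjusted over the list alone, camera adjusted p = 0.204) and mitosis lists (40 tested, 0 called, 0.936) were not among them. Other splits of the same libraries called up to 11 lists, and 0 with an estimated correlation, against 13 and 6 for the dose itself. ANGPTL4 rose to 2.70 ± 0.93 FPKM (fold 2.11, SE 0.16, adjusted p = 3.44e-07), SLC7A11 to 5.72 ± 0.39 (1.74, adjusted p = 2.55e-11) and HMOX1 to 24.1 ± 1.8 (1.34, adjusted p = 1.48e-09). NQO1 (1.17), OSGIN1 (1.13), GCLM (1.12) and SERPINE2, a protease inhibitor (1.08, SE 0.16, chromosome 2, 223975045 to 224039286), rose as well. MMP1 rose by a fold of 1.32 (SE 0.36, adjusted p = 0.0334), a call lost without replicate 1, 2 or 3 at 50 µg/ml (adjusted p = 0.0637, 0.0582 and 0.142), without replicate 1 or 3 at 0 µg/ml (0.119 and 0.102), without the variance trend (0.0515) and with robust eBayes (0.0754). OLR1 (-1.01, adjusted p = 0.00424), NPPB (-0.99), MDGA1 (-0.93), EGR1 (-0.92), MIR503HG (-0.92), RNF207 (-0.82), MEGF6 (-0.81) and TINAGL1 (-0.81) fell. RNF207 overlaps ICMT and RPL22 on the opposite strand, and EGR1 lost its call without replicate 1 at 0 µg/ml (adjusted p = 0.0553) or replicate 3 at 50 µg/ml (0.0639).

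NRF2 targets had 20 of 27 members up and 0 down at 50 µg/ml (23 and 0 adjusted over the list alone; camera adjusted p = 7.2e-36). PPAR targets had 6 up and 0 down (6 and 0 adjusted over the list alone; 0.000132), including CPT1A (0.69) and the carnitine carrier SLC25A20 (0.49). Lysosome genes had 8 up and 0 down (12 and 0; 1.66e-05), the ferroptosis and iron list 6 up and 1 down (8 and 1; 1.25e-06, and 0.0197 without NRF2 genes, lost at adjusted p = 0.0949 with an estimated correlation), and immediate early genes 11 up and 2 down (14 and 3; 6.52e-05), each pair in brackets adjusted over the list alone. The falling member of the iron list was GPX4 (-0.23, lost without replicate 3 at 0 or at 50 µg/ml, adjusted p = 0.0707 and 0.0758), and those of the immediate early list were EGR1 and JUND (-0.46). GPX4, JUND and MCM6 were named after their values were seen. DNA replication had 1 up and 4 down (1 and 10 adjusted over the list alone; 0.000132), with MCM7 (-0.35), RFC4 (-0.17), POLD1 (-0.15) and MCM6 (-0.14) down and ORC6 (0.14) up. The POLD1, MCM6 and ORC6 calls were lost in 8, 21 and 5 of 33 settings (at most adjusted p = 0.153, 0.208 and 0.13). PLIN2 rose to 32.9 ± 1.3 FPKM (fold 0.55, adjusted p = 3.02e-07) and HMGCS1 fell to 6.56 ± 0.12 (-0.61, adjusted p = 0.000188). IL1B (-0.07, adjusted p = 0.755), CASP1 (-0.017, 0.932), ABCA1 (0.21, 0.106) and IL18 (0.18, 0.273) did not pass. IL18 passed without replicate 3 at 100 µg/ml (adjusted p = 0.0485), and ABCA1 did with array weights (0.0269) and limma-voom (0.0458).

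Lists whose call at 50 µg/ml was lost with an estimated correlation included cholesterol biosynthesis (15 down and 0 up, 20 and 0 adjusted over the list alone; camera adjusted p = 1.63e-16, and adjusted p = 0.0585 with an estimated correlation), heat shock (8 up and 0 down, 12 and 0 adjusted over the list alone; 1.25e-06, and adjusted p = 0.0585 with an estimated correlation) and the integrated stress response (7 up and 1 down, 10 and 1 adjusted over the list alone; 0.0151, and adjusted p = 0.0585 with an estimated correlation). Without NRF2 genes the stress response list had an adjusted p of 0.102, and its falling member was SLC7A5 (-0.45). The extracellular matrix list was lost likewise (3 up and 9 down, 4 and 12 adjusted over the list alone; 0.00424, and adjusted p = 0.629 with an estimated correlation). Its median fold was -0.127, and the 3 members that rose against its direction were CCN2 (0.42), LOX (0.37) and MMP14 (0.22). MMP14 was named after its value was seen and lost its call in 4 of 33 settings (at most 0.161, without replicate 3 at 50 µg/ml). So were the interferon list (1 down, IFIT2 at -0.33, and 0 adjusted over the list alone; 0.000176, and adjusted p = 0.133 with an estimated correlation), the respiratory chain (2 down, NDUFA1 at -0.23 and ATP5MC1 at -0.15, and 0 adjusted over the list alone; 0.00023, and adjusted p = 0.564 with an estimated correlation) and ribosomal proteins (0 called; 5.86e-05, and adjusted p = 0.685 with an estimated correlation). IFIT2, NDUFA1 and ATP5MC1 lost their calls in 15, 11 and 19 of 33 settings (at most adjusted p = 0.17, 0.175 and 0.214). The stress response call was lost without replicate 2 at 0 µg/ml or replicate 1 at 50 µg/ml (at most 0.0758), and the ribosomal call without replicate 3 at either dose (at most 0.107). The gene count at 50 µg/ml was 458 without replicate 1 and 500 without replicate 3 at 0 µg/ml, 584 without replicate 2 and 475 without replicate 3 at 50 µg/ml, and 1785 with array weights.

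Of the 906 genes called at 50 µg/ml, 905 had the same direction at 100 µg/ml and 781 were called there in that direction (416 up, 365 down), where independent lists would share 36.4 and 33.7. Both comparisons use the same libraries at 0 µg/ml, which raises such overlap: in 100 simulations with unchanged groups and shared controls, 86.4% of as many top genes had the same direction, and 65% of all genes against 79.6% in the data. Across genes, which are not independent replicates, the folds at both doses had a covariance of 0.0220. The mean in the same simulations was 0.00412, and most of them lay between 0.00096 and 0.0083.

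At 10 µg/ml the genes called were SLC7A11, NQO1, TXNRD1, UGDH and TINAGL1. SLC7A11 rose from 1.36 ± 0.055 to 2.14 ± 0.085 FPKM (fold 0.51, SE 0.063, adjusted p = 0.00498), NQO1 from 62.1 ± 2.0 to 75.9 ± 1.8 (0.29, adjusted p = 0.0278), TXNRD1 by 0.24 (adjusted p = 0.0472) and UGDH, which makes UDP-glucuronate and overlaps UGDH-AS1, by 0.20 (0.0472). TINAGL1 fell by a fold of 0.32 (adjusted p = 0.0472). All of them were called in the same direction at 50 and 100 µg/ml. NRF2 targets were called as a list, with 3 up and 0 down (7 and 0 adjusted over the list alone; camera adjusted p = 2.12e-05), and kept the call with an estimated correlation (0.00407). HMOX1 (0.04, adjusted p = 0.839), PLIN2 (0.08, 0.536), HMGCS1 (-0.29, 0.455), ABCA1 (0.20, 0.503) and IL1B (-0.024, 0.947) did not pass. With 1 library left out 0 to 6 genes were called. The SLC7A11 call was lost in 2 of 33 settings, at a fold of 0.49 without replicate 3 at 0 µg/ml (adjusted p = 0.0588) and 0.48 without replicate 3 at 10 µg/ml (0.061). The count was 0 in both. Calls were lost in 12 of 33 settings for NQO1, 19 for TINAGL1, 21 for TXNRD1 and 25 for UGDH (at most adjusted p = 0.194, 0.345, 0.362 and 0.362).

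Cholesterol biosynthesis was lower as a list at 10 µg/ml (0 genes called of 24, 15 down adjusted over the list alone, median fold -0.15; camera adjusted p = 1.31e-14, and adjusted p = 0.0752 with an estimated correlation). Ribosomal protein genes had negative folds for 48 of 48 (median -0.09; camera adjusted p = 3.11e-16, and adjusted p = 0.452 with an estimated correlation) and the respiratory chain for 28 of 29 (median -0.07; 5.39e-10, and adjusted p = 0.34 with an estimated correlation), with 0 genes called in either, and 0 and 1 down adjusted over the list alone. The NF-kB list (lower; 0.0187, and adjusted p = 0.385 with an estimated correlation), the interferon list (lower; 0.0335, and adjusted p = 0.452) and the mitosis list (higher; 0.00693, and adjusted p = 0.596) were also called at 10 µg/ml. Without replicate 3 at 10 µg/ml these calls were lost, and the NF-kB and interferon calls also without replicate 3 at 0 µg/ml, at most at adjusted p of 0.314, 0.657 and 0.967 over all settings. Disease-associated microglia genes were not called at 10 µg/ml (0.123). Without their NRF2 gene the remaining 11 were called lower (0.0475), and the call was lost at adjusted p = 0.272 with an estimated correlation.

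At 2.5 µg/ml the interferon list was higher (22 of 27 members above 0, median fold 0.07; camera adjusted p = 0.000383, and adjusted p = 0.162 with an estimated correlation), as was the extracellular matrix list (0.0284, and adjusted p = 0.685). Ribosomal proteins (45 of 48 below 0, median fold -0.06; 6.56e-14, and adjusted p = 0.485 with an estimated correlation) and the respiratory chain (1.66e-05, and adjusted p = 0.517) were lower. Without replicate 3 at 2.5 µg/ml these calls and the matrix call were lost, at most at adjusted p of 0.407, 0.812 and 0.632 over all settings, and the matrix call also without replicate 1 at 2.5 µg/ml or replicate 2 at 0 µg/ml. The interferon call was lost without replicate 1 at 2.5 µg/ml (0.0712). At 1 µg/ml ribosomal proteins (0.0254, and adjusted p = 0.826 with an estimated correlation) and neuron markers (0.0326, and adjusted p = 0.131) were higher, with 0 genes called in either by limma or limma-voom. Both calls were lost without replicate 1 at 1 µg/ml or replicate 1 at 0 µg/ml, at most at adjusted p of 0.93 and 0.167 over all settings, the ribosomal call also without replicate 2 at 0 µg/ml, and the neuron call without replicate 3 at 0 µg/ml or replicate 2 at 1 µg/ml. Other splits of the same libraries called up to 6, 7 and 12 lists at 1, 2.5 and 10 µg/ml, against 2, 4 and 7 for the doses themselves. IL1B had 2.40 ± 0.41 FPKM at 1 µg/ml (fold 0.22, adjusted p = 1) and 2.35 ± 0.36 at 2.5 µg/ml (0.19, adjusted p = 0.994).

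Between adjacent doses, 317 genes were called from 10 to 50 µg/ml (169 up, 148 down) and 34 from 50 to 100 µg/ml (27 up, 7 down). From 1 to 2.5 and from 2.5 to 10 µg/ml limma and limma-voom called 0 genes, with 752 and 697 at an unadjusted p under 0.05. From 10 to 50 µg/ml ANGPTL4 (2.02), HMOX1 (1.30) and SLC7A11 (1.24) rose most, and SNORD30 (-0.90), IZUMO4 (-0.81) and SNORD79 (-0.72) fell. SNORD30 and SNORD79 are small nucleolar RNAs inside other genes, so their reads may belong to the host, and IZUMO4 overlaps MOB3A on the opposite strand. SNORD30 lost its call without replicate 2 at 10 µg/ml (adjusted p = 0.0771), without replicate 3 at 50 µg/ml (0.0657) and with thinned reads (0.169), and SNORD79 without replicate 2 at 10 µg/ml (0.0771) and with thinned reads (0.0762). From 50 to 100 µg/ml ANGPTL4 (1.55, adjusted p = 0.000111), HMOX1 (0.84, 6.29e-06) and OSGIN1 (0.65, 0.000347) rose further, and TINAGL1 (-0.32, 0.00543), MCM7 (-0.23, 0.00146) and RUNX2 (-0.32, 0.0237) fell. RUNX2 lost its call in 5 of 33 settings, which were without replicate 2 at 50 µg/ml (adjusted p = 0.2), without replicate 1 or 3 at 100 µg/ml (0.0953 and 0.152), with thinned reads (0.0877) and without the 3 libraries apart on the principal components (0.112). The count from 10 to 50 µg/ml was 113, 79 and 727 without replicate 1, 2 or 3 at 10 µg/ml and 152, 162 and 186 without replicate 1, 2 or 3 at 50 µg/ml.

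Over all doses 1862 genes differed and 3109 had a slope on log2(dose + 1), with 1576 rising and 1533 falling. The steepest rises per unit of log2(dose + 1) were ANGPTL4 (0.52, SE 0.06, adjusted p = 2.91e-06), SLC7A11 (0.37, SE 0.025), HMOX1 (0.32, SE 0.035), OSGIN1 (0.25, SE 0.022) and MMP1 (0.25, SE 0.041, adjusted p = 0.00015). The steepest falls were OLR1 (-0.20, SE 0.025, adjusted p = 4.62e-06), MDGA1 (-0.20, SE 0.027), EGR1 (-0.18, SE 0.023), NPPB (-0.18, SE 0.023) and ELF3 (-0.17, SE 0.02). The slope assumes an even change per step and was not tested against other shapes beyond dose coded by rank or linearly.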

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

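Chosen after the data were seen were limma-voom, thinned reads, the removal of the length and GC trend, the fit without the 3 libraries apart on the principal components (replicate 3 at 2.5, 10 and 100 µg/ml), and lists without NRF2 genes, with either correlation. Of the values recomputed for named genes, 10258 kept their side of the threshold, 518 kept the direction and no longer passed, and 127 passed only in the alternative. Of those called in the main fit or in the alternative, 0 reversed direction. For values called in neither, a change of direction was not counted. Calls at 50 and 100 µg/ml kept their order of size in each alternative, and limma-voom called 897 of the 906 and 1767 of the 1874 genes in the same direction (1233 and 2006 in all), thinned reads 655 and 1433 (737 and 1545 in all). Removing the length and GC trend took 0.3% to 11% of a library's variance. Thinning to the depth of the shallowest library lowers the count of reads per gene by its construction, and a fit of 2 doses has fewer samples; for the other shifts below the cause was not tested.

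Genes called at 10 µg/ml (5) were 2 with no filter, TPM rescaling or quantile normalization, 1 with median-ratio scaling, eBayes without the trend, thinned reads, without the 3 libraries apart on the principal components, or in a fit of 2 doses, 9 with replicate number as a block, and 0 with an absolute log2 fold change of at least 1. With that minimum fold 9 genes were called at 50 µg/ml and 29 at 100 µg/ml. A fit of 2 doses called 1 gene at 1 µg/ml, where limma called 0 with 365 at an unadjusted p under 0.05, and 86 from 10 to 50 µg/ml (317). From 2.5 to 10 µg/ml (0 by limma and limma-voom, 697 at an unadjusted p under 0.05) TPM rescaling called 3, quantile normalization and array weights 2 and length and GC removal 1. Array weights called 1785 at 50 µg/ml (906), 1166 from 10 to 50 µg/ml, 192 from 50 to 100 µg/ml (34) and 3130 over all doses (1862). From 10 to 50 µg/ml thinned reads called 207, length and GC removal 476, and the fit without the 3 libraries 968. Lists called at 1 µg/ml (2) were 1 with a filter of FPKM of at least 1, median-ratio scaling, quantile normalization, thinned reads or length and GC removal. Lists called at 2.5 µg/ml (4) were 2 with array weights or without the 3 libraries, and lists at 10 µg/ml (7) were 4 with array weights. With an estimated correlation 0, 0, 1, 6 and 8 lists were called at 1, 2.5, 10, 50 and 100 µg/ml, and 5 and 7 at 50 and 100 µg/ml when the other lists also lost their NRF2 genes.

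With each library left out in turn, calls ranged from 0 to 0 at 1 and at 2.5 µg/ml, 0 (without replicate 3 at 0 or at 10 µg/ml) to 6 (without replicate 3 at 2.5 µg/ml) at 10 µg/ml, 458 (without replicate 1 at 0 µg/ml) to 1027 (without replicate 3 at 10 µg/ml) at 50 µg/ml, and 1204 (without replicate 3 at 100 µg/ml) to 2011 (without replicate 3 at 2.5 µg/ml) at 100 µg/ml. Between adjacent doses they ranged from 0 to 1 (without replicate 1 at 50 µg/ml) for 1 to 2.5 µg/ml, 0 to 4 (without replicate 3 at 100 µg/ml) for 2.5 to 10 µg/ml, 79 to 727 (without replicate 2 and without replicate 3 at 10 µg/ml) for 10 to 50 µg/ml, and 24 to 42 for 50 to 100 µg/ml. They ranged from 1299 to 1988 over all doses and from 2448 to 3189 for the slope. Lists ranged from 1 to 3, 2 to 4, 5 to 9, 12 to 14 and 13 to 14 from the lowest dose to the highest. Replicate numbers gave no clear pairing of the libraries. Residuals of the 45 pairs with equal numbers had a mean correlation across genes of 0.02 (-0.33 to 0.24), with 10 pairs above 0.1. Other pairs had a mean of -0.01, which is no independent reference because residuals were centred within each dose. Of 18 libraries, 3 correlated best with their own number. With the number as a block 961 genes were called at 50 µg/ml, 1921 at 100 µg/ml and 336 from 10 to 50 µg/ml. Depth limits genes with few reads, such as NLRP3 with 13 to 78 reads per library.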

Other observations

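Chosen after the results were seen were the tests of single libraries, of growth with dose and of sterol loading below. Predictions for depth and for length and GC content were written earlier than these. They still concern patterns and settings chosen after the data were seen. Of the 32 lists, those not described above went both ways or were not called at 100 µg/ml. In the unfolded protein response list 6 of 25 members rose and 0 fell (6 and 2 adjusted over the list alone), among them the stress sensor ERN1 (log2 fold change 0.30), CREB3L2 (0.17), SELENOK (0.15) and SSR1 (0.12), with a camera adjusted p of 0.123. These 4 calls were lost in 1, 7, 3 and 2 of 33 settings, ERN1 without replicate 3 at 100 µg/ml (adjusted p = 0.0706). In the hypoxia and glycolysis list (33 tested, 4 up and 3 down, 5 and 5 adjusted over the list alone, camera adjusted p = 0.649) the glucose transporters SLC2A3 (0.44) and SLC2A1 (0.13), the hexokinase HK1 (0.13) and NDRG1 (0.28) rose, and PFKL (-0.17), PFKFB4 (-0.25) and PDK1 (-0.24) fell. NDRG1, PFKFB4 and PDK1 were named after their values were seen, and lost their calls in 3, 22 and 5 settings (at most adjusted p = 0.0904, 0.19 and 0.0932), as SLC2A1 did in 2 (0.141).

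In the metallothionein list (7 tested, 1 up and 2 down over all genes and adjusted over the list alone, camera adjusted p = 0.417) MT1E (-0.26) and MT1F (-0.41), which bind zinc and copper, fell and the zinc importer SLC39A10 rose (0.16). MT1F and SLC39A10 lost their calls in 8 and 17 settings (at most adjusted p = 0.121 and 0.217), and the metallothioneins are close paralogs that share reads. Nuclear genes of the respiratory chain (29 tested, camera adjusted p = 0.123) had 2 members down (0 adjusted over the list alone), ATP5PO (-0.14) and ATP5F1A (-0.086), lost in 6 and 22 settings (at most 0.117 and 0.162). Ribosomal proteins (48 tested, 0.609) had 0 members called by limma at 100 µg/ml. Among markers of other cell types the astrocyte genes NDRG2 (-0.19) and GLUL (-0.18), the neuronal tubulin TUBB3 (-0.23) and the oligodendrocyte gene CNP (-0.10) fell, which HMC3 cells also express, and NDRG2, GLUL and CNP lost their calls in 3, 11 and 8 settings (at most 0.105, 0.148 and 0.153). Of the mitochondrially encoded list 0 genes were among the symbols listed, and the endothelial list had 4 tested genes.

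The first pattern is the lower cholesterol biosynthesis list. At 100 µg/ml its median log2 fold change over 24 genes was -0.286, and -0.259 (SE 0.044) after removal of the trend with gene length and GC content, which argues against that trend as the whole cause. An SE beside a median, here and for the second pattern, is that of the mean over the list's genes. It comes from the spread between libraries. At 10 µg/ml the median was -0.153, and -0.093 (SE 0.05) without replicate 3. The other two libraries (-0.062 and -0.116) also lay below all 3 at 0 µg/ml (-0.026 to 0.015), and the preset-correlation call held in 33 of 33 settings (at most adjusted p = 1.21e-07), but the change left without that library is within 2 of its errors, so how much of it rests on 1 library stays open. Sterol loading of the cells is a candidate explanation that would lower SREBP2 targets and raise LXR targets: over 13 LXR genes outside both SREBP lists, 3 rose and 1 fell, the median fold was 0.051, and the camera p was 0.181 (0.182 with an estimated correlation), which decides neither way.

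The second pattern is the lower ribosomal protein list at 2.5 and 10 µg/ml. At 2.5 µg/ml its median was -0.062, and -0.011 (SE 0.051) without replicate 3, which is consistent with 1 library as the source, although the error is as large as the change. At 10 µg/ml the median was -0.087, and -0.051 (SE 0.033) after removal of the length and GC trend, which leaves that trend open. An effect of oxLDL that grows with dose would place the libraries at 100 µg/ml below those at 10 µg/ml, but 3 of the 3 at 100 µg/ml lay at or above all 3 at 10 µg/ml, with 1 library of each dose level at -0.043 (mean differences from 0 µg/ml of -0.013 and -0.085, difference 0.072, SE 0.046). The difference lies within 2 of its errors, so this also stays open.

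The third pattern is that many genes were called at 100 µg/ml and few at 10 µg/ml, where 1185 had an unadjusted p under 0.05 against about 606 by chance. With reads thinned to the shallowest library 1545 genes were called at 100 µg/ml and 1 at 10 µg/ml, and with the length and GC trend removed 2177 and 4, which argues against unequal depth and against that trend as the cause. The counts do not show a threshold above 10 µg/ml, since SLC7A11 and the NRF2 list were called there, the list with library means of 0.107, 0.119 and 0.116 against -0.017 to 0.013 at 0 µg/ml. A response that grows with dose is a hypothesis and may be tested with cultures treated separately. The labels give 1 batch value, so a difference in handling between doses was not tested.

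For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real and the highest other counts of genes were 0 and 0 at 1 and 2.5 µg/ml, 5 and 0 at 10 µg/ml, 906 and 1 at 50 µg/ml, 1874 and 0 at 100 µg/ml, 0 and 0 for 1 to 2.5 µg/ml, 0 and 1 for 2.5 to 10 µg/ml, 317 and 0 for 10 to 50 µg/ml, and 34 and 0 for 50 to 100 µg/ml (the limma counts of 0 stand beside 365, 531, 752 and 697 genes at an unadjusted p under 0.05 and 0 by limma-voom). For lists with the preset correlation they were 2 and 6, 4 and 7, 7 and 12, 13 and 11, and 13 and 13 from the lowest dose to the highest. With an estimated correlation they were 0 and 1, 0 and 1, 1 and 1, 6 and 0, and 8 and 0. Over all doses, 100 splits of the 18 libraries were counted, the real one among them. The real count of 1862 genes stood against at most 3 in another split, and the 3109 genes with a slope against at most 89. Random grouping of all 18 libraries thus gave no gene count near the real ones over all doses and for the slope. The splits treat libraries as exchangeable, so they cannot separate dose from a difference between cultures if the libraries of a dose share 1 culture.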
